A study of Mus musculus with 16 samples.

How the data were processed

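The series measured messenger RNA of oligodendrocytes, the myelin-forming glia of the brain, taken from mouse brain by magnetic cell sorting. The 16 libraries were directional and made from poly(A) RNA, and they came from male mice in 4 groups of 4: wild type (C57BL/6J Jcl) and App knock-in mice (App NL-G-F/NL-G-F, homozygous), each on a control diet or a high-fat diet. The App knock-in carries a humanised amyloid-β region with disease mutations in the mouse App gene. In the names used here, WT_NCD and WT_HFD are wild type on the control and the high-fat diet, App_NCD and App_HFD are the knock-in on each diet, and the number after a group name is the replicate number in the labels. Per the labels' protocols, the control diet gave 12.5% of its energy as fat (345.0 kcal per 100 g) and the high-fat diet 60.0% (524 kcal per 100 g), for 6 months from 2 months of age, so mice were sampled at 8 months. The labels gave no batch, litter, day or hour of sampling, and no replicate number occurs in more than 1 group, so nothing was blocked or paired.

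The deposited table held an estimated count per gene and library, per the submitters' processing notes made by trimming with fastp 0.23.2, alignment to mm10 with HISAT2 2.2.1 and assembly and quantification with StringTie 2.2.1; bedtools 2.25.0 was also named. The annotation the authors counted against was not given in the sources used here. All values were whole numbers as deposited, so rounding to whole numbers changed nothing. StringTie derives a count from read coverage and transcript length, and it can divide reads between overlapping or near-identical genes. Values of genes with close copies are therefore uncertain wherever they appear below. The genes meant are MHC class I, ribosomal protein, haemoglobin and immunoglobulin genes, and the overlapping gene IDs of Nnt. The table held 53801 genes with an ID and a symbol, and 53620 of the IDs (99.7%) were in GENCODE mouse release 21, from which coordinates were taken. A symbol was carried by more than 1 ID in 125 cases.

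Totals ran from 64538297 to 217925484 counts per library, so counting error was small beside the spread between mice for all but rare genes. Genes with low counts were removed with filterByExpr, which left 21768, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust dispersions, on all 16 libraries in 4 groups with 12 residual degrees of freedom, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The contrasts were the diet effect in each genotype, the genotype effect on each diet, and their interaction. Standard errors of log2 fold changes were derived from the log2 fold change and the quasi-likelihood F value. CPM is the count scaled to the TMM-adjusted library total as edgeR defines it, and scores of gene lists are means of log2 CPM with a prior count of 0.5.

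There were 35 gene lists, written before the data were examined: 13 of cell type markers and others of lipid metabolism, amyloid processing, glial disease states, stress, hormone response, energy metabolism and passenger genes. Each was tested with camera (limma) with a preset correlation of 0.01, beside camera with an estimated correlation and fry, with adjustment over the lists within a contrast. The App level and the marker scores were compared by exact two-sided permutation tests, whose smallest p for 4 libraries against 4 is 0.0286. The genes named in the text follow a rule also set before the data were examined. It takes App, and the 12 highest and 12 lowest log2 fold changes among called genes with a mean of at least 1 CPM and a proper symbol. It also takes up to 6 called members of each list by adjusted p (or, where none passed, up to 4 by level), the 10 smallest p where fewer than 10 genes passed, and up to 10 genes called in both contrasts of a kind. The text describes fewer than the rule takes, and names outside it are said to be so. The rule was also applied to the fit without App_NCD 553.

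The alternatives also set then were DESeq2 1.42.0, limma-voom with quality weights, RLE scaling, library totals alone, no filter, a filter of at least 10 counts in all libraries, non-robust dispersions, the 8 libraries of a pair alone, an unadjusted p with a 2-fold change, and each library left out in turn. A further one added the first principal component of 8 other-cell marker scores as a covariate. Chosen after seeing the data were every fit without App_NCD 553 that the plan did not hold, scaling to the myelin and mature oligodendrocyte list, fits without WT_HFD 2 and 16 or WT_NCD 4 and 11 as well as App_NCD 553, and the diet effect averaged over the genotypes.

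The procedure was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed per contrast. With 16 libraries the test recovered 32.8% of genes changed 2-fold and 89.4% of those changed 4-fold in the control-diet genotype contrast, and 31.3% and 83.3% in the wild-type diet contrast. With App_NCD 553 left out the shares were 79.1% and 95.5%, and 77.6% and 92.4%. Apart from the changed genes, all simulated libraries shared the same mean profile, with the spread fitted to the real ones. The simulation therefore spread the deviation of App_NCD 553 over all libraries, and does not show what 1 aberrant library does to the real test. Of all calls, 2.53% to 6.02% were false, and none of the unshifted lists was called. The simulated genes varied independently of each other, so this says little on false list calls in the real libraries. For diet in wild type, 34 other splits of the real libraries each called at least 1 list, and up to 15. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.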

Results

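RNA of sorted oligodendrocytes was sequenced from 16 male mice: 4 wild type on the control diet (WT_NCD), 4 wild type on the high-fat diet (WT_HFD), 4 App knock-in on the control diet (App_NCD) and 4 App knock-in on the high-fat diet (App_HFD). Totals ran from 98588561 to 217925484 counts in WT_NCD and from 90220118 to 101737328 in WT_HFD. They ran from 69772745 to 101709022 in App_NCD and from 64538297 to 84114322 in App_HFD, so the App libraries were on the whole less deep. The design asks how the knock-in, the diet and their combination change the oligodendrocyte transcriptome.

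The library App_NCD 553 stood apart from the other 15. It had 18928 genes with a count above 0, against 27151 to 30617 in the others, and 39.4% of its counts were from mitochondrially encoded genes, against 1.22% to 4.62%. Its rank correlation with other libraries was 0.671 to 0.778, while that among the others was at least 0.888. It kept the high level of App-specific genes described below (disease-associated microglia score 8.41). The common biological coefficient of variation was 36.5% with it and 26.3% without it, so each main count is also given without this library. That alternative was planned for diet in App, genotype on the control diet and the interaction, and chosen after seeing the data for the other contrasts. The WT_HFD libraries 2 and 16 had 0.929% and 0.515% haemoglobin counts, against 0.015% to 0.119% in the others.

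**Figure D1:**
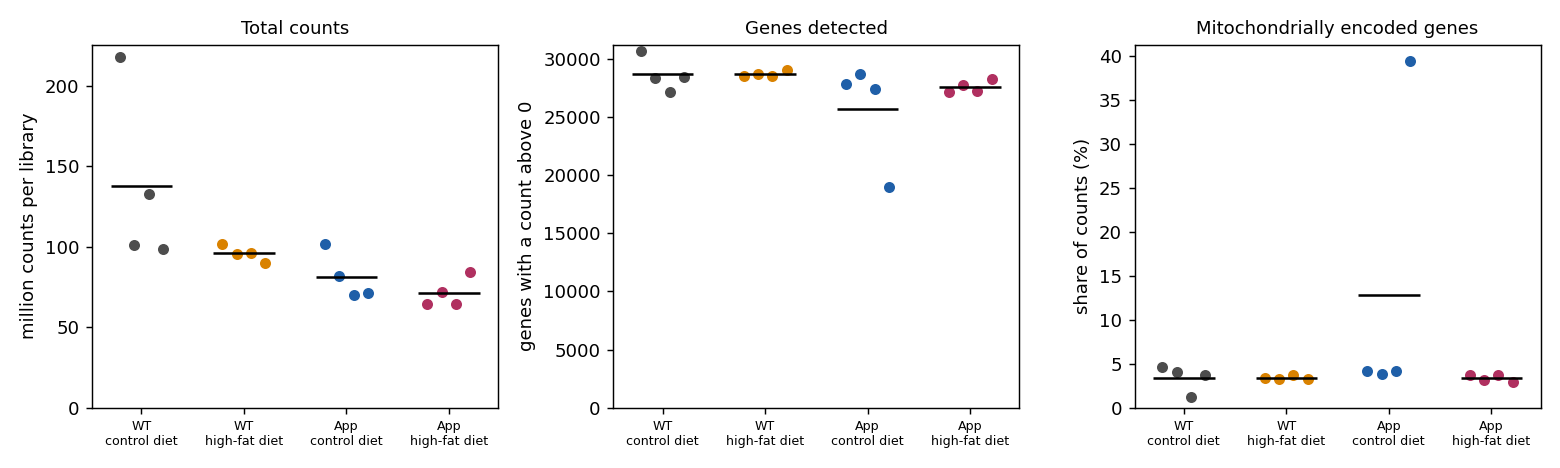
Total counts, genes with a count above 0 and percent of counts from mitochondrially encoded genes, for each of the 16 libraries (points) in the 4 groups, with the group mean as a line. App_NCD 553 is the point at 18928 genes and 39.4%.

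App itself (ENSMUSG00000022892, mm10 chromosome 16, 84949685 to 85173766, minus strand), which encodes the amyloid precursor, was lower in the knock-in libraries. On the control diet it was at 2220 ± 102.4 CPM (SD, n = 4) in App_NCD and 3158 ± 670.6 CPM in WT_NCD, 0.714-fold by means of log2 CPM (exact permutation p = 0.0286, two-sided). On the high-fat diet it was at 2356 ± 168.1 CPM in App_HFD and 3113 ± 281 CPM in WT_HFD, 0.758-fold by the same measure (exact permutation p = 0.0286). In edgeR the log2 fold change was -0.51 ± 0.155 (SE, adjusted p = 0.0535) on the control diet and -0.40 ± 0.154 (adjusted p = 0.153) on the high-fat diet. Without App_NCD 553 the edgeR adjusted p values were 0.0322 and 0.0457. Without it the exact permutation p on the control diet was 0.0571. With scaling to the oligodendrocyte marker list the control-diet difference was 0.03 on the log2 scale, and -0.18 without App_NCD 553 (exact permutation p = 0.257). That on the high-fat diet was -0.24 with this scaling (exact permutation p = 0.0286). The knock-in alters the coding sequence of App under its own promoter, so its level does not by itself check the labels.

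**Figure D2:**
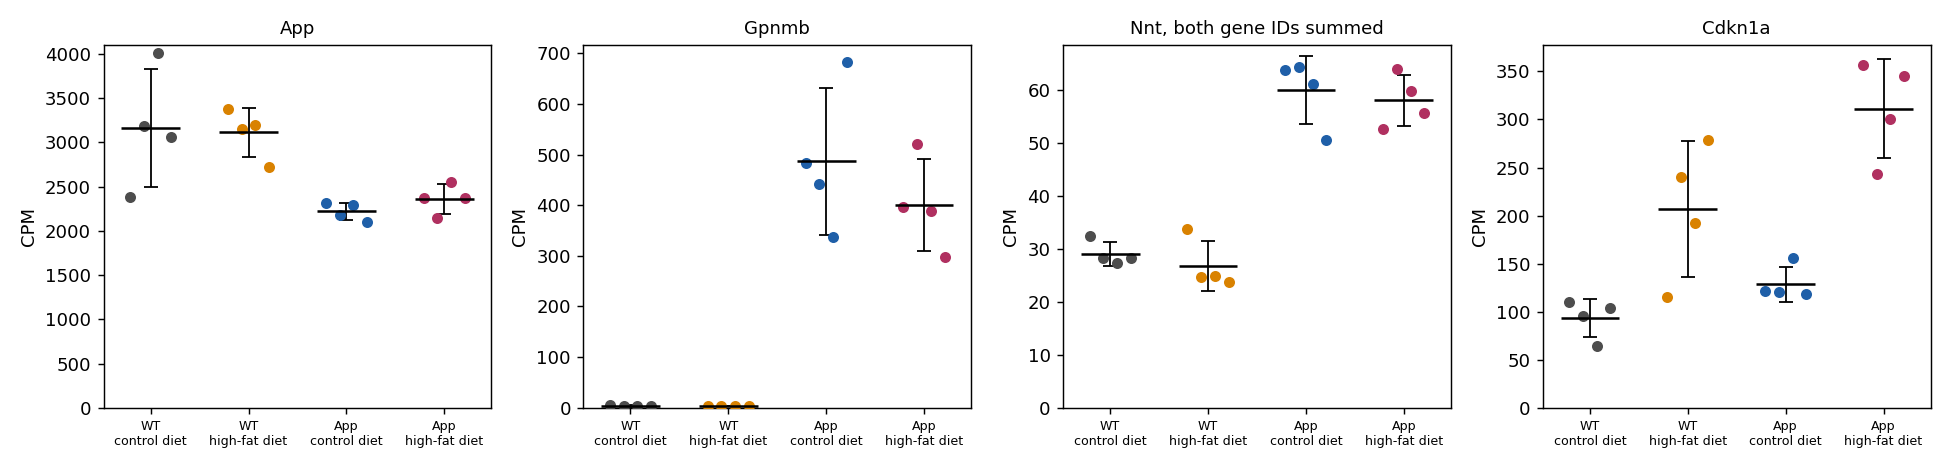
CPM per library (points, n = 4 per group) with mean and SD (bars) of App, Gpnmb, Nnt summed over its overlapping gene IDs, and Cdkn1a. Mean App is lower and Gpnmb and Nnt are higher in the App groups, and mean Cdkn1a is higher on the high-fat diet.

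On the control diet, genes of the disease-associated microglial state were among those highest in App libraries relative to wild type. Cst7, a cystatin, was at 929.4 ± 161.7 CPM in App_NCD and 0.98 ± 0.470 CPM in WT_NCD (SD, n = 4). Gpnmb, a glycoprotein of lipid-laden phagocytes, was at 486.5 ± 144.6 and 3.76 ± 1.51 CPM, and Itgax, the integrin CD11c, at 653.4 ± 225.7 and 6.16 ± 2.11 CPM. Of the 24 listed genes of this state, 23 rose in edgeR, with a median log2 fold change of 3.08. The log2 fold changes were 9.88 ± 0.633 for Cst7 (SE, adjusted p = 1.44e-07), 7.01 ± 0.336 for Gpnmb (adjusted p = 1.42e-08), 6.56 ± 0.451 for Spp1, which encodes osteopontin, and 2.65 ± 0.164 for the growth factor Csf1. Camera called the list (adjusted p = 4.9e-41, and 0.0165 with an estimated correlation). Without App_NCD 553 the adjusted p was 0.0828 with an estimated correlation. All 23 passed when adjusted over the list alone.

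Homeostatic microglial markers rose less. Of 15 such genes 9 rose, 13 when adjusted over the list alone, with a median log2 fold change of 1.35; the list's adjusted p was 1.4e-08, and 0.323 with an estimated correlation. C1qb, a complement subunit, rose by 1.77 ± 0.289 (adjusted p = 0.00119), Olfml3 by 1.66 ± 0.239 and the fractalkine receptor Cx3cr1 by 1.03 ± 0.247 on the log2 scale, while Tmem119, named after its values were seen, had -0.35 (adjusted p = 0.662). Among wild-type libraries, WT_NCD 4 and WT_HFD 16 had the highest homeostatic microglia scores (8.38 and 8.15). Of 8 border macrophage genes 0 passed in edgeR (median 0.09; camera adjusted p = 0.635).

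Genes raised in oligodendrocytes of disease models, some of which microglia also express, rose in part on the control diet: 7 of 20, and 9 when adjusted over the list alone (camera adjusted p = 0.000539, and 0.323 with an estimated correlation). The protease inhibitor Serpina3n rose by 1.03 ± 0.246 (adjusted p = 0.0171), the MHC class I gene H2-D1 by 1.58 ± 0.302 and cathepsin B (Ctsb) by 1.85 ± 0.234 on the log2 scale. The complement gene C4b, chosen after its values were seen, had 0.69 ± 0.378 (adjusted p = 0.257), and 1.00 ± 0.124 (adjusted p = 5.98e-05) without App_NCD 553. Of 30 interferon and MHC class I genes 10 rose, 17 when adjusted over the list alone (median 0.86, adjusted p = 2.82e-09, and 0.299 with an estimated correlation), among them Nlrc5 (1.24 ± 0.232), an activator of MHC class I genes. Cell cycle genes rose in 11 of 20 cases, 15 when adjusted over the list alone (median 1.80; adjusted p = 8.75e-11, and 0.323 with an estimated correlation), such as Top2a (2.19 ± 0.454) and Tyms (1.39 ± 0.202). Among wild-type libraries the cell cycle score was highest (up to 2.22) in WT_NCD 4 and WT_HFD 16, which also had the highest homeostatic microglia scores, and 0.83 to 0.94 in the other 6. The interferon score was 3.94 and 3.92 in these 2 and 3.36 to 3.62 in the others, and the immediate early score 7.67 and 7.38 against 6.82 to 7.14. The disease-associated oligodendrocyte score was likewise highest in these 2, at 6.18 and 6.26 against 5.78 to 6.09. Whether the genes of that list rose in oligodendrocytes or in microglia was therefore not determined. Of 77 cytosolic ribosomal protein genes 19 rose, and 32 when adjusted over the list alone (median 0.89; adjusted p = 8.75e-11, and 0.494 with an estimated correlation); these have many pseudogene copies and are uncertain. The score of this list was 8.31 and 8.45 in App_NCD 538 and 545 but 7.04 and 6.52 in 537 and 553, against 6.67 to 7.08 in WT_NCD. Immediate early genes, which respond to tissue dissociation as well as to signals in life, rose in 5 of 20 cases, and in 11, with 2 lower, when adjusted over the list alone (adjusted p = 4.59e-05, and 0.474 with an estimated correlation), with Egr2 at 2.15 ± 0.184 and Atf3 at 1.22 ± 0.304.

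None of 30 myelin and mature oligodendrocyte genes passed in edgeR, which recovered 4.48% of simulated 1.5-fold changes in this contrast with 16 libraries. That simulation called 89 genes, against 1826 in the real contrast, so its cutoff on the unadjusted p was stricter. The share may therefore be too low for the real contrast. Of the 30, 27 were lower in App: Mbp had -0.22 ± 0.181 (adjusted p = 0.456) and Mal -0.38 ± 0.169 on the log2 scale, and the list median was -0.42 (camera adjusted p = 0.00026, and 0.494 with an estimated correlation). Without App_NCD 553 the median was -0.31 (adjusted p = 0.000124, and 0.521 with an estimated correlation), and the score difference went from -0.52 to -0.27. Among precursor markers the proteoglycan Cspg4 (1.94 ± 0.433) and Serpine2 (1.95 ± 0.213) rose and Cspg5 (-0.99 ± 0.201) fell, with 13 of 16 not passing (camera adjusted p = 0.635). In lipid metabolism, 3 of 25 cholesterol genes fell, 4 when adjusted over the list alone (median -0.38; adjusted p = 0.000619, and 0.387 with an estimated correlation), among them the synthesis enzymes Sqle (-0.48 ± 0.113) and Lss (-0.45 ± 0.107). The cholesterol score was 3.86 in App_NCD 553, 5.07 to 5.27 in the other App_NCD libraries and 5.33 to 5.49 in WT_NCD. The list median was -0.30 without App_NCD 553 (adjusted p = 0.000192, and 0.311 with an estimated correlation). Sqle and Lss turned to 0.10 and 0.12 when all 16 libraries were scaled to the oligodendrocyte marker list. With this scaling the median of all genes was 0.511, and 0.249 without App_NCD 553, so part of that shift rests on this library. The fatty acid synthesis genes Acss2 (-0.74 ± 0.183) and Acacb (-0.98 ± 0.25) fell, 2 of 24 and 4 when adjusted over the list alone (adjusted p = 0.0381, and 0.393 with an estimated correlation). The lipid droplet protein Plin2 (1.23 ± 0.193) and Ucp2 rose while the β-oxidation enzyme Acaa2 (-1.04 ± 0.215) fell. The score of the fatty acid oxidation list was 4.7 in App_NCD 553, 5.11 to 5.19 in the other App_NCD libraries and 5.32 to 5.48 in WT_NCD. The lysosomal hydrolase Hexa (2.19 ± 0.33) was among 7 of 31 sphingolipid genes that rose, with 1 that fell (camera adjusted p = 0.665). Among wild-type libraries the sphingolipid score was highest in WT_NCD 4 (6.22), against 6.08 to 6.15 in the others, WT_HFD 16 (6.15) included. Microglial genes rose in the same contrast, so the cell type in which these lipid genes changed was not determined.

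Vascular markers were lower in App libraries on the control diet. Of 14 endothelial genes 4 fell, 8 when adjusted over the list alone (median -0.90; adjusted p = 5.31e-05, and 0.387 with an estimated correlation), such as Vwf, which encodes von Willebrand factor (-2.07 ± 0.521, adjusted p = 0.0232), and Tek, the angiopoietin receptor (-1.43 ± 0.325). Of 10 pericyte and smooth muscle genes 3 fell, 7 when adjusted over the list alone (adjusted p = 0.000138, and 0.323 with an estimated correlation), among them Tagln (-1.06 ± 0.242). Of 15 astrocyte genes 3 fell, among them Aldh1l1 (-1.02 ± 0.213), and no neuronal gene passed. The ependyma and choroid plexus score had an App minus wild-type difference of -0.63 (exact permutation p = 0.0571). Without App_NCD 553 it was -0.42 (exact permutation p = 0.0857). Of 13 mitochondrially encoded genes 8 rose, such as mt-Nd4 (4.26 ± 1.15). Without App_NCD 553, 0 of them passed in edgeR and mt-Nd4 had 0.44 ± 0.37 (edgeR, adjusted p = 0.438).

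In all, edgeR called 1826 of 21768 genes for genotype on the control diet, 1416 higher and 410 lower in App (77.5% higher). Without App_NCD 553 it called 3900 genes, 2288 higher and 1612 lower (58.7% higher), and 1734 genes were in both sets in the same direction. With library totals 525 were higher and 316 lower (62.4% higher), and with oligodendrocyte scaling 4427 and 80 (98.2%), so the balance depends on the scaling. Without WT_NCD 5, 11 or 12 it called 969, 945 or 939. The counts were 505 with only the 8 libraries of the pair and 82 with other-cell content as a covariate, a component that separates the genotypes itself.

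On the high-fat diet genes of the same microglial state were again among those highest in App relative to wild type. Cst7 rose by 9.29 ± 0.619 on the log2 scale (adjusted p = 2.85e-07, n = 4 per group), Gpnmb by 6.80 ± 0.334, Itgax by 6.77 ± 0.359 and Clec7a, the dectin-1 receptor, by 4.98 ± 0.352. Of the 24 disease-associated microglial genes 23 rose (median 3.40; camera adjusted p = 1.2e-50, and 0.00647 with an estimated correlation; without App_NCD 553 that p was 0.0677), all 23 also when adjusted over the list alone. Of 15 homeostatic markers 13 rose (median 1.32; adjusted p = 2.3e-13, and 0.134 with an estimated correlation), with C1qb at 2.06 ± 0.291. Csf1 (2.40 ± 0.162), Serpina3n (1.15 ± 0.246), H2-D1 (1.96 ± 0.305) and H2-K1 (1.48 ± 0.247) rose as on the control diet, and Apoe, the lipid carrier of glia, rose by 1.29 ± 0.344 (adjusted p = 0.0326). The disease-associated oligodendrocyte list had 6 of 20 genes higher, and 10 with 1 lower when adjusted over the list alone (adjusted p = 9.3e-06, and 0.134 with an estimated correlation).

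Interferon and MHC class I genes rose in 11 of 30 cases (adjusted p = 4.68e-10, and 0.134 with an estimated correlation), immediate early genes in 11 of 20 (adjusted p = 1.22e-09, and 0.247 with an estimated correlation) and cell cycle genes in 7 of 20 (adjusted p = 1.06e-12, and 0.134 with an estimated correlation) on the high-fat diet. The counts adjusted over the list alone were 16, with 1 lower, then 15 and 13. Ribosomal protein genes rose in 18 of 77 cases (adjusted p = 3.22e-20, and 0.253 with an estimated correlation). Fatty acid synthesis genes fell in 3 of 24 cases, 4 when adjusted over the list alone (adjusted p = 0.0017, and 0.155 with an estimated correlation), among them Acacb (-1.05 ± 0.25) and Elovl7 (-0.74 ± 0.203). None of the cholesterol or myelin genes passed in edgeR. Camera called both lists lower: cholesterol with a median of -0.17 (adjusted p = 0.0131, and 0.422 with an estimated correlation) and myelin with -0.14 (adjusted p = 0.021, and 0.674 with an estimated correlation). The border macrophage list was higher, with 8 of 8 genes positive and 0 passing (median 0.56; adjusted p = 0.0101, and 0.319 with an estimated correlation). Pdgfra, the receptor that marks oligodendrocyte precursors, fell by 1.46 on the log2 scale (SE 0.282, adjusted p = 0.00469) while Cspg4, also a precursor marker, rose by 2.15 ± 0.436. The amyloid-processing protease Adam17 (0.57 ± 0.119) rose and the γ-secretase subunit Aph1c (-0.76 ± 0.202) fell, the 2 of 19 genes of that list to pass (camera adjusted p = 0.79).

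Choroid plexus and erythroid genes were lower in App libraries on this diet. Of 10 ependymal and choroid plexus genes 4 fell, 5 when adjusted over the list alone (adjusted p = 6.45e-05, and 0.134 with an estimated correlation), with Ttr, the choroid plexus transthyretin, at -1.16 ± 0.295 and Kl at -1.27 ± 0.265. All 5 erythroid genes fell (adjusted p = 9.27e-05, and 0.252 with an estimated correlation), such as Hbb-bs (-3.59 ± 0.817), for which WT_HFD had 1154 ± 1236 CPM; the haemoglobin share was high in WT_HFD 2 and 16 alone. Of 14 endothelial genes 2 fell (adjusted p = 0.000386, and 0.319 with an estimated correlation), one of them Pecam1 (-0.90 ± 0.232), which had 0.22 with the other-cell covariate. In all, 1554 genes were called by edgeR on the high-fat diet, 1108 higher and 446 lower, and 4307 (2401 higher, 1906 lower) without App_NCD 553, all 1554 among them. With library totals it called 1176, 639 higher and 537 lower (54.3% higher), and with oligodendrocyte scaling 905 higher and 39 lower (95.9%). Without WT_HFD 2, 3 or 15 it called 869, 949 or 996, and without App_HFD 547 or 559 it called 890 or 891. With other-cell content as a covariate 44 were called.

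Log2 fold changes for genotype on the control and high-fat diets correlated across 21768 genes (Pearson r = 0.599, Spearman rho = 0.525; genes are not independent replicates), and the contrasts shared no library. Of the called genes, 881 were higher and 123 lower in App on both diets, where 72.1 and 8.4 would be shared by independent lists of these sizes, and 0 were called in opposite directions. Pianp, a neuronal PILRα ligand, was among the highest on both diets (6.78 ± 0.333 and 6.66 ± 0.332), as was Dkk2, a Wnt pathway modulator (7.21 ± 0.413 and 6.01 ± 0.393).

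**Figure D3:**
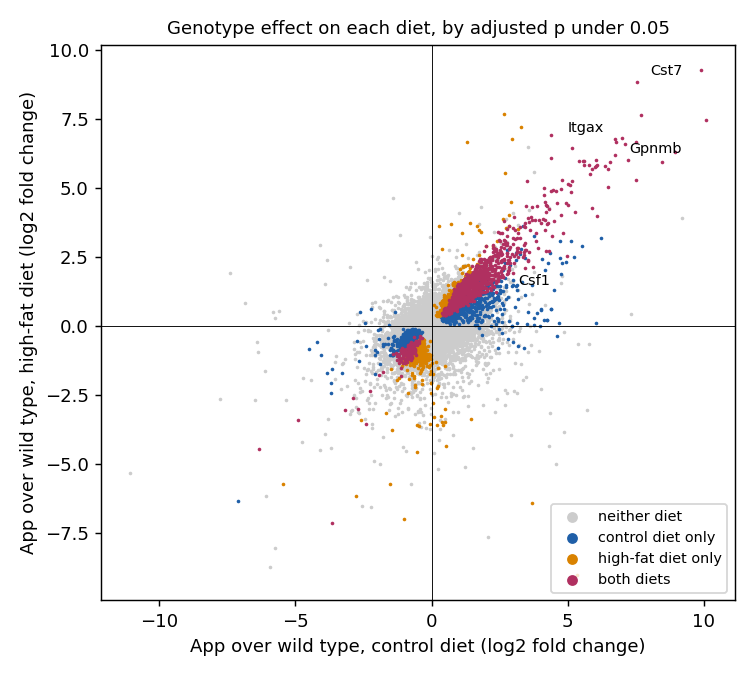
Log2 fold change of App over wild type on the control diet (horizontal) and the high-fat diet (vertical) for 21768 tested genes, coloured by whether the adjusted p was under 0.05 on neither, either or both diets. Cst7, Gpnmb, Itgax and Csf1 are named, and no gene called on both diets lies in opposite quadrants.

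In the comparison of the diets, edgeR passed no gene in either genotype. In wild type the smallest p values included those of Sh2b2, an adaptor of insulin receptor signalling (1.04 ± 0.215 on the log2 scale, n = 4 per group), Cdkn1a, the cell cycle inhibitor p21 (1.14 ± 0.241), and Ada, adenosine deaminase (0.86 ± 0.183), each with an adjusted p of 1. In App, Cdkn1a had 1.27 ± 0.242, Pla2g3, a secreted phospholipase, 1.22 ± 0.247, and Spns2, a transporter of sphingosine-1-phosphate, 0.81 ± 0.134 (adjusted p = 0.15), while Scd1, the stearoyl-CoA desaturase, had -0.57 ± 0.118 (adjusted p = 0.33). The myelin gene Mbp had 0.13 ± 0.181 in wild type and 0.21 ± 0.181 in App. edgeR called 0 genes in either genotype, with 419 at an unadjusted p under 0.05 in wild type and 2586 in App; DESeq2 called 7 and 102, and limma-voom with quality weights 6 and 161. In simulated data with 16 libraries edgeR recovered 1.49% and 2.99% of 1.5-fold changes in these contrasts. Those simulations called 79 and 83 genes, against 0 in the real contrasts, so their cutoff on the unadjusted p was looser. Both shares may therefore be too high for the real contrasts. Without App_NCD 553 edgeR again called 0 in both, with 1139 and 1576 at an unadjusted p under 0.05, and DESeq2 called 49 and 116.

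Of the 35 lists, the glucocorticoid response genes had the smallest p for diet in wild type, with 16 of 16 genes positive and a median log2 fold change of 0.29 (adjusted p = 3.02e-11, and 0.0886 with an estimated correlation; 1 passed when adjusted over the list alone). In App 15 of 16 were positive with a median of 0.43 (adjusted p = 8.46e-07, and 0.815 with an estimated correlation; 7 passed when adjusted over the list alone). In wild type the neuron list was higher (median 0.34; adjusted p = 2.18e-05, and 0.0489 with an estimated correlation), the border macrophage list lower (median -0.41; adjusted p = 7.04e-08, and 0.0886 with an estimated correlation), and the erythroid list higher with the haemoglobin counts of WT_HFD 2 and 16 (median 2.51; adjusted p = 7.04e-08, and 0.131 with an estimated correlation). The cholesterol list was lower (median -0.13; adjusted p = 0.00168, and 0.493 with an estimated correlation), with Srebf2 at -0.18 ± 0.288 and Hmgcs1 at -0.03 ± 0.132. Camera also called the homeostatic microglia list lower in wild type, with 15 of 15 genes negative (median -0.24; adjusted p = 0.00274, and 0.742 with an estimated correlation). It called higher the lists of newly formed oligodendrocytes (median 0.10; adjusted p = 0.0103, and 0.0886 with an estimated correlation), precursors (0.19; 0.00469 and 0.131) and disease-associated oligodendrocytes (0.07; 0.00274 and 0.418). In App the disease-associated oligodendrocyte list (median 0.23; adjusted p = 0.0103, and 0.931 with an estimated correlation) and the phospholipid list (0.29; 0.0326 and 0.931) were higher, and the erythroid list lower (-1.10; 0.0395 and 0.931). These medians were 0.14 (adjusted p = 0.0403, and 0.802 with an estimated correlation), 0.06 (0.0442 and 0.53) and -0.85 (0.127 and 0.854) without App_NCD 553. In App the myelin list was higher (median 0.29; adjusted p = 0.00388, and 0.931 with an estimated correlation), with 0 genes passing in edgeR. Without App_NCD 553 its median was 0.18 (adjusted p = 0.0015, and 0.854 with an estimated correlation), and its score difference went from 0.39 to 0.14. In App, too, the mitochondrially encoded list was lower (median -3.07; adjusted p = 6.34e-05, and 0.931 with an estimated correlation) through App_NCD 553. Camera called 9 lists in wild type and 6 in App, but 24 and 18 of the 35 splits of the same libraries called as many.

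The diet by genotype interaction was not detectable gene by gene: edgeR called 0 genes (639 at an unadjusted p under 0.05; DESeq2 called 3 and limma-voom with quality weights 0), and 0 without App_NCD 553 (614 at an unadjusted p under 0.05). The smallest p values among named genes included those of the immunoglobulin gene Igha (-10.09 ± 2.41) and the erythroid genes Alas2 (-3.95 ± 1.08) and Hba-a2 (-3.63 ± 0.995), each with an adjusted p of 0.851. Of the lists, camera called the erythroid (median -3.63; adjusted p = 1.23e-06, and 0.817 with an estimated correlation) and the mitochondrially encoded one (median -3.03; adjusted p = 2.2e-05, and 0.817 with an estimated correlation). The erythroid score was high in WT_HFD 2 and 16 (10.28 and 9.34, against 5.77 and 7.12 in WT_HFD 3 and 15). Without App_NCD 553 camera called 4 lists, of which the erythroid list alone was among these 2. Log2 fold changes for diet in wild type and App, which share no library, had r = 0.112 across genes (rho = 0.052), and r = 0.236 (rho = 0.226) without App_NCD 553. It was 0.046 without WT_HFD 16, 0.048 without App_HFD 561 and 0.074 without WT_NCD 4. Among genes with an unadjusted p under 0.05 in both genotypes, 87 changed in the same direction and 9 in opposite directions, where independence gives 24.9 each; without App_NCD 553 the numbers were 258, 13 and 40.2.

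The diet effect averaged over the genotypes, a contrast chosen after seeing the data, called 10 genes in edgeR, all higher on the high-fat diet (1504 at an unadjusted p under 0.05). They included Cdkn1a (1.21 ± 0.171, adjusted p = 0.036), Pla2g3 (1.05 ± 0.174), Sh2b2 (0.98 ± 0.152), Prkar1b, a regulatory subunit of protein kinase A (0.94 ± 0.153), Pdxk, pyridoxal kinase (0.89 ± 0.146), Ada (0.85 ± 0.13) and the inositol phosphatase Inpp5j (0.70 ± 0.113). Cdkn1a was at 93.55 ± 20.2 CPM in WT_NCD, 206.2 ± 70.6 in WT_HFD, 128.8 ± 17.95 in App_NCD and 311.4 ± 51.8 in App_HFD (SD, n = 4). Without App_NCD 553, 57 genes were called, 53 higher and 4 lower, among them the neuronal tubulin Tubb3 (0.65 ± 0.0847), the triglyceride lipase Pnpla2 (0.50 ± 0.0817) and, lower, Scd1 (-0.44 ± 0.0692) and Sptlc3, a subunit of serine palmitoyltransferase (-0.60 ± 0.112). Of 16 glucocorticoid response genes 8 rose when adjusted over the list alone, and 1, Cdkn1a, over all genes (median 0.38; adjusted p = 4.68e-12, and 0.171 with an estimated correlation). The count of all genes called for this contrast, 10 in the main fit, was 0 with library totals alone, without a low-count filter or with the other-cell covariate. It was also 0 when any of WT_NCD 4, 5, 11 or 12, WT_HFD 3, 15 or 16, App_NCD 537 or 538, or App_HFD 547, 560 or 561 was left out.

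Across the 13 marker lists and 4 pairwise contrasts, 0 of 52 differences in mean score passed adjustment (smallest adjusted p = 0.186). An exact permutation p of 0.0286, the smallest that 4 against 4 allows, was reached by 8 comparisons. Adjustment over 52 could be passed only if many more reached it, so this outcome was nearly fixed by the design. The disease-associated microglia score was 8.87 ± 0.32 in App_NCD and 5.22 ± 0.44 in WT_NCD, and 8.82 ± 0.34 in App_HFD and 5.09 ± 0.32 in WT_HFD (SD, n = 4; exact permutation p = 0.0286 each). The newly formed oligodendrocyte score was higher on the high-fat diet, with 4.58 ± 0.12 in WT_HFD and 4.34 ± 0.05 in WT_NCD, and 4.45 ± 0.06 in App_HFD and 4.02 ± 0.51 in App_NCD (exact permutation p = 0.0286 each). The difference in App went from 0.43 to 0.18 without App_NCD 553 (exact permutation p = 0.0286). The pericyte score was 3.23 ± 0.4 in App_NCD and 4.23 ± 0.12 in WT_NCD (exact permutation p = 0.0286). On the high-fat diet the App minus wild-type differences at that p were 1.46 for homeostatic microglia, -0.35 for neurons and -0.69 for ependyma and choroid plexus.

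**Figure D4:**
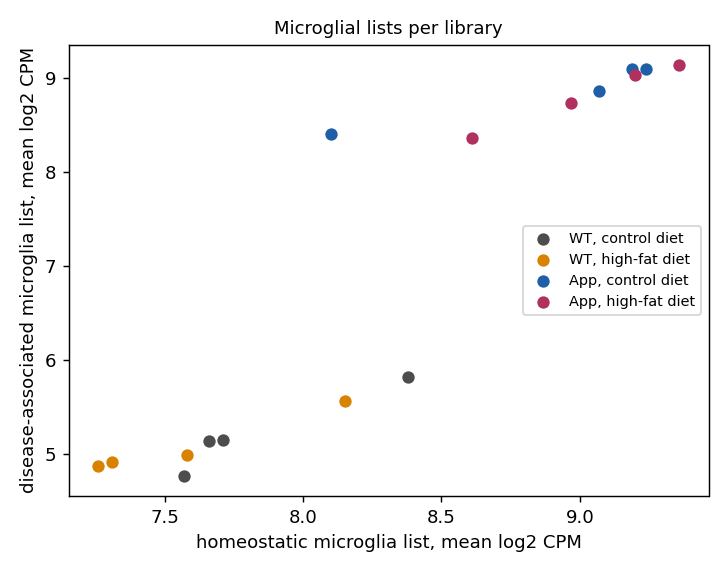
Mean log2 CPM of the homeostatic microglia list (horizontal) and the disease-associated microglia list (vertical), 1 point per library, coloured by group. Wild-type libraries lie between 4.77 and 5.82 on the vertical axis and App libraries between 8.37 and 9.14, at overlapping homeostatic scores only for App_NCD 553.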

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

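The values put to the outlier test in this part were chosen after the data had been seen, while the list tests were planned. In App_NCD, replicate 553 lay far from the other 3 libraries in genes with a count above 0 (18928, others 27384 to 28672) and in TMM factor (0.493, others 0.986 to 1.04). It also did so in the share of mitochondrially encoded counts (39.4%, others 3.8% to 4.17%), the share in the 10 most abundant genes (42.8%, others 8.78% to 10.2%) and the homeostatic microglia score (8.1, others 9.07 to 9.24). In WT_HFD, replicate 16 lay above the others in the lymphocyte and granulocyte score (1.05, others -1.03 to -0.68). In App_HFD, replicate 561 lay below the others in the erythroid score (4.43, others 5.7 to 5.91). The outlier test was run on 20 values in each of 4 groups, and chance picks out about 1 in 20 groups.

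The diet effect on the erythroid list differed between the genotypes by the interaction test (median -3.63; adjusted p = 1.23e-06, and 0.817 with an estimated correlation). The erythroid score was 10.28 and 9.34 in WT_HFD 2 and 16, and 5.77 and 7.12 in WT_HFD 3 and 15. The diet effect also differed by this test for the mitochondrially encoded list (median -3.03; adjusted p = 2.2e-05, and 0.817 with an estimated correlation), whose values in App_NCD rest on replicate 553.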

How the results depend on the processing

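The runs without App_NCD 553 that add a further change, the scaling to the oligodendrocyte list and all runs of the averaged diet effect were chosen after seeing the data. The median of all genes for genotype, -0.016 and 0.005 with TMM (control and high-fat diet), was -0.293 with library totals on the control diet, and 0.511 and 0.162 with oligodendrocyte scaling, so directions are relative to that. For genotype on the control diet (main 1826 genes) the counts were 841 with library totals, 3398 with DESeq2, 7233 with limma-voom, 82 with the other-cell covariate, 505 with 8 libraries and 4507 with oligodendrocyte scaling. Without App_NCD 553 they were 2776 with oligodendrocyte scaling, 4937 with DESeq2, 214 with the covariate, 4021 without WT_HFD 2 and 16 and 2955 without WT_NCD 4 and 11. For genotype on the high-fat diet (main 1554) they were 2508 with DESeq2, 6680 with limma-voom, 44 with the covariate, 4816 with 8 libraries and 944 with oligodendrocyte scaling. Without App_NCD 553 they were 2736, 5189 and 439 in the same order of scaling, DESeq2 and covariate, 3334 without WT_HFD 2 and 16 and 4915 without WT_NCD 4 and 11. Leaving out 1 library gave 939 to 3900 and 869 to 4307 genes.

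For diet, edgeR's 0 became 7 and 102 with DESeq2 and 6 and 161 with limma-voom (wild type and App), and 49 and 116 with DESeq2 without App_NCD 553. It was 7 in wild type without WT_HFD 2 and 16 and App_NCD 553, and 274 and 1039 at an unadjusted p under 0.05 with a 2-fold change. For the interaction DESeq2 gave 3, or 6 without App_NCD 553, and the unadjusted 2-fold rule 520. Leaving out 1 library gave 0 for these 3 in edgeR. For the averaged diet effect (main 10) the count was 0 with library totals, no filter, the covariate, oligodendrocyte scaling, and without WT_NCD 4 and 11 and App_NCD 553. It was 111 with DESeq2, 511 with limma-voom, 358 with DESeq2 without App_NCD 553, 96 without WT_HFD 2 and 16 and App_NCD 553, 363 with the unadjusted rule, and 0 to 57 when leaving out 1 library. Lists called with an estimated correlation were 1 for diet in wild type, 0 in App, 1 for genotype on each diet and 0 for the interaction and the averaged effect. Fry called 0 for diet in wild type, 0 in App, 14 and 12 for genotype on the control and high-fat diets, 0 for the interaction and 1 for the averaged effect. Lists called when leaving out 1 library were 7 to 11, 4 to 10, 14 to 18 and 15 to 19 for diet in wild type, diet in App and genotype on the control and high-fat diets. They were 2 to 7 for the interaction and 3 to 13 for the averaged effect.

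The correlation of diet effects was 0.028 with the strict filter and 0.046 (without WT_HFD 16) to 0.236 (without App_NCD 553) when leaving out 1 library, and that of genotype effects 0.515 to 0.687. With oligodendrocyte scaling the App difference on the control diet was 0.034, and -0.184 without App_NCD 553 (exact permutation p = 0.257). Sqle and Lss were at 0.104 and 0.116 with this scaling of all 16 libraries. With TMM the App difference was -0.458 without App_NCD 553 (exact permutation p = 0.0571). Pecam1 on the high-fat diet was at 0.218 with the covariate and 0.129 without App_NCD 553 as well. Of 122 named gene values past the threshold 22 passed in each alternative, 100 were lost in at least 1 and 3 reversed; 38 of 68 others passed in at least 1. The cause was not tested.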

Other observations

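In this part, the tests of microglial make-up, oligodendrocyte share, strain, shared Nnt reads, time of day and cell isolation were chosen after the result was seen, as were the split counts for called genes. Further lists moved in part with genotype. Of 26 lipid export genes 4 rose and 2 fell on the control diet (camera adjusted p = 0.381), and 5 rose and 1 fell on the high-fat diet (adjusted p = 0.0204, and 0.297 with an estimated correlation). The lysosomal lipase Lipa rose on the control diet (1.25 ± 0.292), the cholesterol carrier Npc2 rose on the high-fat diet (1.30 ± 0.299), and Clu, which encodes clusterin, fell on both (-0.85 ± 0.218 and -0.91 ± 0.218). Among wild-type libraries the lipid export score was highest in WT_NCD 4 and WT_HFD 16 (6.85 and 6.77, others 6.68 to 6.73). These libraries also had the highest homeostatic microglia scores, so the cell type in which these genes changed was not determined. Among 18 genes near App on chromosome 16, the protease Adamts1 rose on both diets (1.37 ± 0.164 and 1.22 ± 0.164; list adjusted p = 0.233 and 0.713). Among 16 clock genes on the control diet, Cry1 fell (-0.80 ± 0.135) and Bhlhe40 and Bhlhe41 rose (0.89 ± 0.176 and 1.69 ± 0.384; list adjusted p = 0.686). Of 20 insulin and FOXO genes, Pik3ip1, an inhibitor of PI3 kinase, fell on both diets (-0.66 ± 0.109 and -0.39 ± 0.109; list adjusted p = 0.523 and 0.508).

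On the control diet the phospholipid list had a median of -0.28 with 0 of 32 genes passing in edgeR (adjusted p = 0.0241, and 0.571 with an estimated correlation). Without App_NCD 553 that median was -0.15 (adjusted p = 0.0722, and 0.307 with an estimated correlation). The nuclear oxidative phosphorylation list had a median of -0.19 with 0 of 52 passing in edgeR (adjusted p = 0.00975, and 0.71 with an estimated correlation). Its score was 5.55 and 5.56 in App_NCD 537 and 553 but 6.53 and 6.51 in 538 and 545, against 6.30 to 6.45 in WT_NCD. The ER stress (0.836), oxidative stress (0.738), iron (0.381), newly formed oligodendrocyte (0.836) and lymphocyte (0.863) lists were not called, by camera adjusted p. Among newly formed oligodendrocyte genes the calcium channel Itpr2 rose on both diets (0.68 ± 0.163 and 0.58 ± 0.163). The substrain list held 6 genes under 7 tested gene IDs, as Nnt has overlapping IDs. Of these genes, Entpd4 fell on the control diet (-1.07 ± 0.226, with a camera adjusted p of 0.27 for the list). Entpd4 (-0.81 ± 0.225), Cyfip2 (-0.72 ± 0.156) and Crb1 fell on the high-fat diet (list adjusted p = 0.0491, and 0.182 with an estimated correlation). Crb1 was barely detected, at a mean of 0.182 CPM in WT_HFD and 0.0142 CPM in App_HFD. On the high-fat diet the lymphocyte gene Cd79a fell (-2.04 ± 0.546), and the high score of WT_HFD 16 belongs to that contrast.

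The microglial genes were higher in App libraries in a form that more microglia of the wild-type kind alone would not give. The disease-associated score minus the homeostatic score rose by 2.58 on the control diet and 2.27 on the high-fat diet (exact permutation p = 0.0286 each), where unaltered microglia would leave it level. The homeostatic score itself rose by 1.07 (exact permutation p = 0.0571) and 1.46 (exact permutation p = 0.0286). More microglia together with a changed state therefore stays open. A lower share of oligodendrocyte RNA would raise all other cells alike, but the homeostatic score rose over the mean of 6 other-cell scores by 1.57 and 1.85 (exact permutation p = 0.0286 each). Part of these differences was a fall of the other-cell scores. On the control and high-fat diets they changed by -1.03 and -0.55 (endothelium), -1 and -0.48 (pericyte), -0.63 and -0.69 (ependyma), -0.34 and -0.31 (astrocyte), -0.18 and -0.35 (neuron), and 0.14 and 0.01 (precursor). After all libraries were thinned to the smallest total, the disease-associated medians were 3.09 and 3.36 with 23 genes called on each diet, which argues against depth. These values are consistent with microglia or microglial RNA of an altered state in the App preparations, and whether it comes from attached cells or from oligodendrocytes themselves stays open.

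Among substrain genes, Nnt, chosen after its values were seen, differed between the genotypes. Summed over its overlapping IDs, Nnt was 2.06-fold higher in App on the control diet and 2.19-fold on the high-fat diet (exact permutation p = 0.0286 each), so reads shared between the IDs do not account for it. Of the 5 other substrain genes, 2 (Entpd4 and Cyfip2) parted the genotypes without overlap over 15 libraries, against 10.6% of tested genes (binomial p = 0.091). Over 16 libraries it was 1 of 5, against 6% of tested genes (binomial p = 0.266). A strain difference between the knock-in line and the wild-type mice cannot be told apart from the knock-in, since strain and genotype coincide in this design.

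Glucocorticoid response genes, a list picked out of 35 after the results were seen, were higher on the high-fat diet. The immediate early score differed by -0.03 (95% interval -0.32 to 0.27), which argues against a response to cell isolation of that size. With other-cell content as a covariate and without App_NCD 553 the list median was 0.37, against 0.41 before, and camera still called it (adjusted p = 8.45e-12, and 0.189 with an estimated correlation). The median SE grew from 0.145 to 0.203, fry's adjusted p went from 0.0211 to 0.215, and Cdkn1a went from 1.19 ± 0.171 to 1.00 ± 0.226 (edgeR adjusted p = 0.00991 and 0.691), so these calls ended as the error widened and, for Cdkn1a, the value fell. Of 15 clock genes 0 passed in edgeR when adjusted over the list alone (2 at an unadjusted p under 0.05, with Tef at 0.31), but only 9 of the intervals stayed within 0.41, so time of day, which may differ between groups, cannot be told apart from diet.

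Other splits of the same libraries were counted for each set of calls, the real split included. Where edgeR called 0 genes, each split reaches that count by construction, so the count says nothing on chance: diet in wild type (35 of 35 splits; highest other 0; 419 genes at an unadjusted p under 0.05; DESeq2 7), diet in App (35 of 35; highest other 1; 2586; DESeq2 102) and the interaction (60 of 60; highest other 0; 639; DESeq2 3). For genotype on the control diet 1 of 35 splits gave as many as the real 1826, with 543 as the highest other. Without App_NCD 553 the figures were 1 of 35, 3900 and 2881. Both of these other splits put WT_NCD 4 with App_NCD 537, 538 and 545 against WT_NCD 5, 11 and 12 (with App_NCD 553 in the first), so they keep most of the genotype grouping. For genotype on the high-fat diet they were 1 of 35, 1554 and 0, and without App_NCD 553 1 of 35, 4307 and 1. For diet averaged over the genotypes they were 1 of 60, 10 and 0, and without App_NCD 553 1 of 60, 57 and 17. The glucocorticoid list had the smallest camera p in 1 of 60 splits with 16 libraries (next 3.14e-11) and in 1 of 60 without App_NCD 553 (next 5.91e-14). For diet within wild type its camera p was 8.63e-13 in the real split and 1.72e-12 in the next. Within App these were 2.42e-08 and 9e-07. Without App_NCD 553, however, another split within App gave a camera p of 1.09e-16, against 1e-12 in the real one. As many lists were called in 24 of 35 splits for diet in wild type (real 9, highest other 15), 18 of 35 for diet in App (6 and 12) and 59 of 60 for the interaction (2 and 15), so chance is not excluded there. It was 1 of 35 for genotype on the control diet (17 and 14) and on the high-fat diet (19 and 17). Without App_NCD 553 the real split called 16 lists on the control diet, but other splits called 17 and 18. On the high-fat diet the real split then called 19 lists and the highest other 17. For the genotype counts where 1 split of 35 reached the real value, chance is excluded at the 0.05 level for each count taken alone. For the lists called on the control diet without App_NCD 553, chance is not excluded. For the glucocorticoid list and the averaged diet effect, chosen after seeing the data, the splits do not repeat that choice, so chance is not excluded.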
